A study of Mus musculus with 800 samples.

How the data were processed

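The samples were the 800 capture chambers of 1 Fluidigm C1 high-throughput chip, loaded with GFP-positive cells that were Hoechst-positive and DRAQ7-negative, from the vomeronasal organs of 7 male mice heterozygous for an Omp-GFP allele, aged 66 days. Each chamber was deposited as 1 sample, and chambers were grouped by the capture state in its labels: 394 single-cell, 325 empty, 63 multiple-cell and 18 putative single-cell chambers. Receptor calls gave 126 V1R and 23 V2R cells as deposited, and 236 and 82 under the corrections below. The values were counts of 5-base unique molecular identifiers per gene and chamber, deposited as 1 table of 28963 genes with no normalization. The submitters' processing notes name bcl2fastq, UMI-tools 0.5.3, STAR 2.5.4b, featureCounts 1.6.1 from Subread, SAMtools 1.5 and the GRCm38 (mm10) mouse genome, with no order or settings. The submitters' naming of the table mentions fractional counting of reads that map to several places, but all values were whole numbers, from 0 to 662, so how such reads were assigned is not known. Of the table's columns, 1 held reads assigned to no chamber and was not used here.

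Total counts per chamber ran from 4501 to 319287, and all 394 single-cell chambers passed a minimum of 1000 counts and 500 genes. Genes detected were also compared after thinning each chamber to 10000 counts. Multiple-cell chambers were kept apart by their label, and no doublet caller was run. Gene positions, biotypes and transcript sequences came from GENCODE vM21 on GRCm38, where 27802 genes matched by symbol and 452 of 461 receptor genes had a position. Receptor genes were those with symbols of the Vmn1r, Vmn2r and Fpr families, and pseudogenes were known by symbol or biotype, which left 316 functional genes (197 V1R, 114 V2R, 5 Fpr) and 139 pseudogenes outside family C.

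A cell's receptor was the receptor gene outside V2R family C with the highest count, called if it had at least 10 counts and 50% of these receptor counts. A second receptor needed at least 10 counts and 10% of the top count. Receptor genes within 1 Mb of a neighbour formed a genomic cluster. Family C counted as present at 3 counts. Shares have exact Clopper-Pearson 95% intervals, ratios of summed counts have exact conditional binomial 95% intervals, and medians have order-statistic intervals. All of these treat each count as a separate molecule and each cell as drawn alone.

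V1R and V2R cells were compared on counts summed over the cells of a class, scaled to the class total without receptor genes. The size rule took a gene with at least 50 counts over both classes that was at least 2-fold apart in all cells and 1.5-fold apart the same way in title numbers 1 to 10 and in 11 to 20. A class with 0 counts was set to a floor of 3 counts. No test was made and each group of chambers counted as 1 unit, since the labels do not link chambers to the 2 pools of mice. Gene lists were set against 10000 random lists of genes matched by expression. Cells were clustered without receptor genes on log counts per 10000, with 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.5. A group of cells was named only from markers fixed beforehand, of which at least 3 had to be detected.

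The receptor call, the size rule, the lists, the markers and the choice of named genes were set before the data were examined. The rule named the 10 V1R and 10 V2R genes called in most cells, with ties by summed count, every Fpr gene, the 5 most called pseudogenes, the 5 genomic clusters with most called cells, the 12 genes with the largest fold each way, and members of the lists used here that the size rule took. The corrections for cross-talk and for shared sequence, and the minimum of 10 counts in 25% of cells, were chosen after the data were seen. With that minimum the size rule took 496 genes as deposited (234 higher in V1R and 262 in V2R cells). With both corrections as well it took 199 genes of 17059 tested (84 higher in V1R and 115 in V2R cells), given elsewhere as a share of tested genes. The cross-talk correction kept a receptor count only where it was at least 3 times the 75th percentile of the other chambers of its title row and of its title number, plus 5. Receptors were taken to share sequence where at least 1% of the 50-base words of either one's transcripts occurred in the other's, and those sharing with a cell's top receptor were left out of its receptor total and its second receptors.

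The alternatives tried were other minima for counts, genes and receptor shares, other linking distances, corrections for the limited number of identifiers (1024), separate title numbers, other scalings, other Leiden settings, other pseudogene definitions, the putative single-cell chambers added, sustentacular-like cells left out, and the corrections above. The genes Trpc2, S100b, Sox10, Mup4 and Epha6 and the hemoglobin genes of the fixed lists were not analysed here.

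The steps were tested on simulated data. With Poisson counts at the observed depths, the size rule recovered 94% of 100 genes simulated at 3-fold and 94% of 100 at 6-fold, and took 104 unchanged genes of 14661 tested. The simulation held no cell-to-cell variation beyond Poisson counting, so it does not measure how many unchanged genes are taken in the observed data. With 394 simulated chambers that held 1 receptor at the observed top counts over the mean receptor counts of empty chambers, 30.7% were called, the called receptor was right in 100% of these, and the top receptor was right in 98.7% of all. A mean background is spread over many receptor genes. In the observed data 16% of empty chambers were called as deposited, at a median top count of 139.5. The 100% therefore does not measure how often a called receptor is wrong in the observed data. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and matplotlib 3.10.9.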

Results

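Vomeronasal sensory neurons detect pheromones in mice, and each neuron is thought to transcribe a single vomeronasal receptor gene chosen from the large V1R and V2R families or the small formyl peptide receptor (Fpr) family. Cells carrying GFP under the olfactory marker protein gene Omp were sorted from 7 adult male mice, pooled as 3 and 4 animals, and loaded on 1 microfluidic chip with 800 capture chambers for 3′ end single-cell RNA sequencing. The labels called 49.3% of the chambers single cell, 40.6% empty, 7.88% (63 chambers) multiple cells and 2.25% (18 chambers) putative single cell. They did not say which chamber received which pool, so chambers of a state were not counted as replicates and no test between groups was made. The intervals given are exact 95% intervals that cover counting error only.

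Single-cell chambers held a median total count of 149648 [145760–152757], with quartiles of 128852 and 173563, and a median of 6031 genes above 0. Multiple-cell chambers held a median of 181883 counts and putative single-cell chambers 118238. Empty chambers held a median of 20731 [19345–22254], with quartiles of 14682 and 38584. Omp, the marker of mature olfactory and vomeronasal neurons, had a median count of 87 in single-cell chambers and 21 in empty chambers, which set the background level. The mitochondrial share of counts had a median of 1.21% in single-cell chambers and 3.41% in empty chambers. In 25 empty chambers (7.69% [5.04–11.1]) the total reached the lower quartile of the single-cell chambers, 128852 counts.

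**Figure D1:**
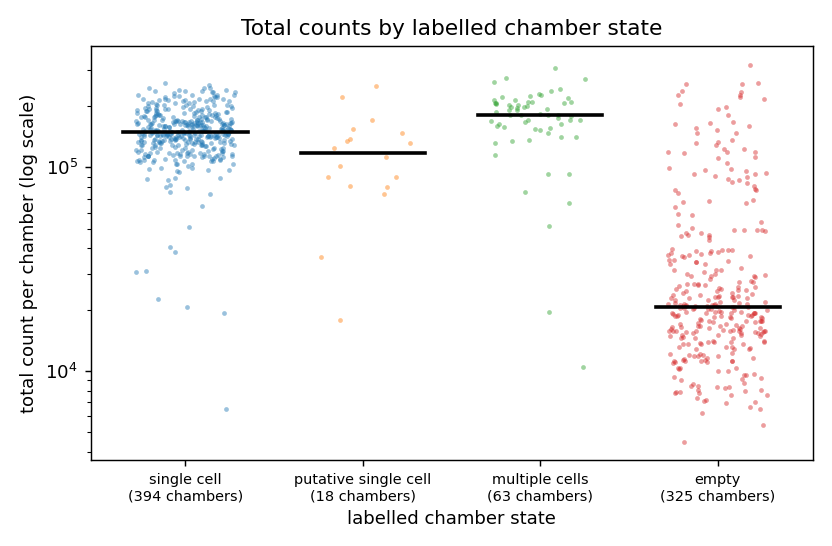
Total count per chamber (log axis) for each labelled chamber state, with 1 point per chamber and a bar at the median. The median was 149648 in single-cell chambers and 20731 in empty chambers, with 25 empty chambers at or above 128852.

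The first question was which receptor class each cell expressed. V1R genes were the called receptor in 83.4% [76.5–89] of the called cells and V2R genes in 15.2% [9.91–22] (23 cells), while 1 cell was called for Fpr3 and 1 for Fpr-rs3. V2R cells held a median of 78 counts of Gnao1, the G protein alpha subunit of the basal neuron layer, and 8 of Gnai2, its counterpart in the apical layer, while V1R cells held a median of 1 count of Gnao1. Gnao1 exceeded Gnai2 in 23 of 23 V2R cells (100% [85.2–100]) and in 0% [0–2.89] of V1R cells. The Fpr3 cell, where Fpr3 held 68.6% of the receptor counts, had 6 counts of Gnai2 and 73 of Gnao1. The Fpr-rs3 cell, where Fpr-rs3 held 68.7%, had 74 counts of Gnai2 and 0 of Gnao1.

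A receptor was called in 38.3% [33.5–43.3] of single-cell chambers, where it held a median of 62.7% of the receptor counts, and in 16% [12.2–20.4] of empty chambers. Receptor transcripts of strongly expressing cells also appeared in other chambers. For the top receptors of cells with at least 150 counts of them, 7.31% of the other chambers in the same title row and 11.04% of those with the same title number held at least 10 counts, against 3.00% of chambers sharing neither. When such cross-talk was removed and receptors sharing transcript sequence with the top receptor were left out, 320 single-cell chambers had a called receptor (81.2% [77–85]), with a median share of 81.2%. Under these corrected calls V2R cells were 82 of 320 (25.6% [20.9–30.8]) and V1R cells 73.8%. Gnao1 then exceeded Gnai2 in 68 of 82 V2R cells (82.9%) and in 3 V1R cells (1.27%). Empty chambers were called in 61.5% under the same corrections, on a median top count of 43 against 166.5 in single-cell chambers.

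**Figure D2:**
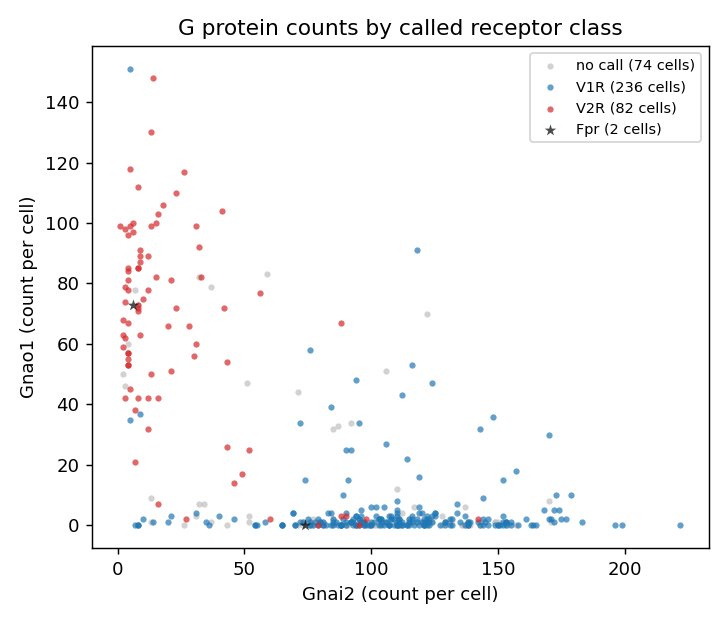
Counts of Gnai2 (horizontal) and Gnao1 (vertical) in each of the single-cell chambers, coloured by the class of the corrected receptor call. Cells called V1R lie mostly along the Gnai2 axis and cells called V2R along the Gnao1 axis, with Gnao1 above Gnai2 in 82.9% of V2R cells and 1.27% of V1R cells.

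The repertoire question was how widely the receptor genes were used, and whether functional genes inside and outside genomic clusters differed, which the series title raises. The most used V1R genes were Vmn1r85 (chromosome 7, 13083313–13095173, GRCm38), Vmn1r51 (chromosome 6, 90122596–90132264), Vmn1r89 (chromosome 7, 13213020–13220657), Vmn1r236 (chromosome 17, 21282942–21294007) and Vmn1r71 (chromosome 7, 10744543–10754364), each called in 6 cells. The median count in those cells was 293.5 for Vmn1r85, 361.5 for Vmn1r51 and 169.5 for Vmn1r89. Vmn1r28 and Vmn1r32 were called in 4 cells each, and Vmn1r185, Vmn1r218 and Vmn1r84 in 3. The most used V2R gene was Vmn2r93 (chromosome 17, 18298099–18331914), called in 3 cells, followed by Vmn2r107, Vmn2r120 and Vmn2r25 in 2 cells each. Vmn2r90, Vmn2r62, Vmn2r17, Vmn2r100, Vmn2r55 and Vmn2r53 were called in 1 cell each, and Vmn2r17 reached the highest receptor count of any cell, 495. Some ranks depended on the correction, since Vmn1r89 was called in 10 cells, Vmn1r35 went from 0 cells to 9, and Vmn2r20, Vmn2r82 and Vmn2r36 from 0 to 4. Among Fpr genes, Fpr3 summed to 477 counts over the single-cell chambers. Fpr-rs6 summed to 25 counts, Fpr-rs3n-ps1 to 17, Fpr-rs4 to 2 and Fpr-rs7 to 2. Fpr1, Fpr2 and the family C gene Vmn2r7 were not analysed here.

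Of the functional receptor genes, 81 were called in at least 1 cell (25.6% [20.9–30.8]), and 140 (44.3% [38.7–50]) under the corrected calls. The share was 31% [24.6–37.9] for functional V1R genes and 15.8% [9.63–23.8] for functional V2R genes, and the corrected calls gave 46.2% and 41.2%. Pseudogenes were rarely the called receptor, at 1 gene (0.719% [0.0182–3.94] of pseudogenes). That gene was Vmn1r-ps144 (chromosome 17, 20926165–20938090), annotated as a transcribed unprocessed pseudogene and called in 2 cells at a median of 143.5 counts. The corrected calls added 1 cell each for Vmn2r-ps159, Vmn1r-ps24, Vmn2r-ps21 and Vmn1r-ps145, making 5 pseudogenes (3.60% [1.18–8.19]).

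The 5 genomic clusters with most called cells were on chromosome 7 (7231327–13220657, 28 cells), chromosome 17 (17703747–21314912, 27 cells), chromosome 13 (22057346–23269474, 20 cells), and chromosome 6 (89698719–90243214, 15 cells, and 56924015–58495247, 14 cells). The small V1R cluster of 9 genes on chromosome 6 (66552180–66810609) held 9 cells, and 32 under the corrected calls. A V1R cluster of 75 genes on chromosome 7 (20099680–24063554) held 10 cells, and 30 corrected. Both then ranked above the chromosome 6 clusters named before, which held 21 and 22 cells corrected. Clustered genes accounted for 96.7% [92.4–98.9] of the called cells. Only 6 functional receptor genes had no neighbour within 1 Mb. Vmn1r90 (chromosome 7, 14555474–14563506) was called in 3 cells and Vmn2r120 (chromosome 17, 57506453–57545505) in 2. The other isolated genes had no called cell: Vmn2r121 on chromosome X reached 10 counts in 17 cells, and Vmn2r118 summed to 3 counts. Vmn2r122 (at least 10 counts in 12 cells) and Vmn1r186 (in 2 cells) lay on unplaced scaffolds, so their true neighbours are not known. Cells per functional gene were 0.465 for clustered and 0.833 for isolated genes, and 0.994 and 1 under the corrected calls. The shares of genes called were 25.5% [20.7–30.7] and 33.3% [4.33–77.7], and 44.5% [38.9–50.2] and 33.3% with corrected calls, so the order turned and the few isolated genes set no difference. With genes linked up to 2 Mb apart, both called isolated genes joined a cluster and the clustered share was 100%.

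**Figure D3:**
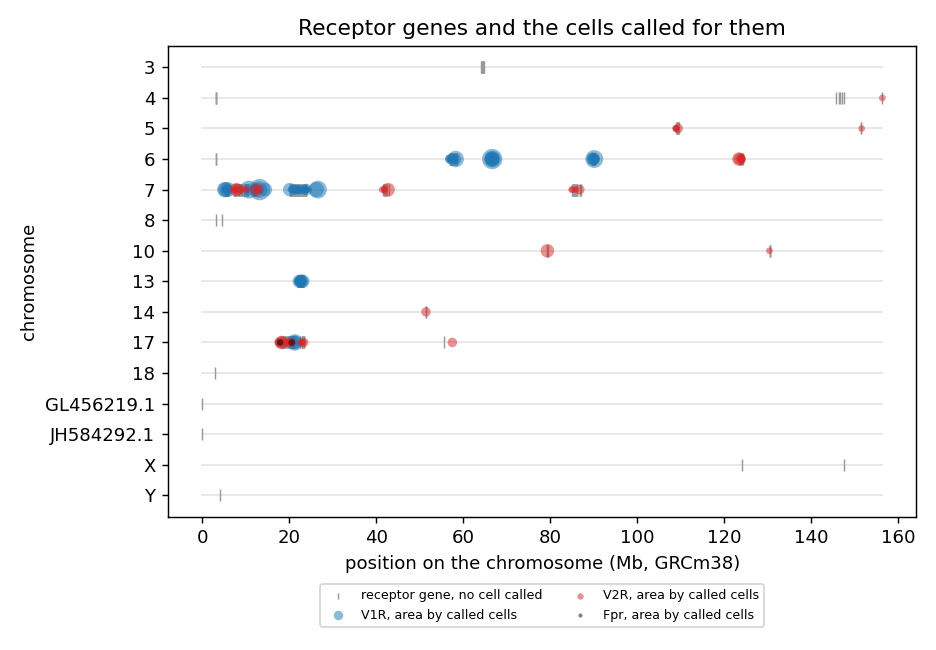
Receptor genes along the chromosomes (Mb, GRCm38), with grey ticks for genes without a called cell and circles with area by the number of cells in the corrected calls. Chromosome 7 (7231327–13220657) and chromosome 17 (17703747–21314912) hold the clusters with most cells, 59 and 43.

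Clustering the single cells on genes other than receptors gave 4 groups, which addressed whether receptor class matched the rest of the transcriptome. A V1R-type-like group (59.1% of cells) was marked by Gnai2, Meis2 and Nrp2 (at least 10 counts in 86.3% of its cells against 38.5% of others). A V2R-type-like group of 76 cells was marked by Gnao1 (98.7% against 13.2%), Tfap2e (52.6% against 2.20%) and Robo2 (71.1% against 5.03%). An immature-like group of 62 cells had Gap43, a growth cone protein of young neurons, in 59.7% against 26.2%, Stmn2 in 91.9% against 58.7% and Dcx in 48.4% against 23.8%, and kept a median Omp count of 85.5. A sustentacular-like group of 23 cells had Cbr2 (91.3% against 16.2%), Cyp2a5 (60.9% against 0.809%), Sox2 (78.3% against 0.539%), Krt8 and Krt18, with a median Omp count of 16. The immune marker Cd74 was as specific to that group (86.96% against 1.08%). Of the V1R calls, 80.2% fell on V1R-type-like, 16.7% on immature-like, 3.17% on sustentacular-like and 0% on V2R-type-like cells, and V2R calls on 22 V2R-type-like cells and 1 immature-like cell. Receptor class matched the majority class of its group in 99.3% [96.3–100.0] of cells, and in 94.3% [91.2–96.6] under the corrected calls. The majority was set from the same calls, and V1R calls in the immature-like and sustentacular-like groups counted as matches. V1R cells were 83.4% of called cells as deposited and 73.8% corrected, so shares near these would arise without any link.

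The next comparison asked which genes other than receptors set V1R cells apart from V2R cells. V1R cells had higher summed counts of Gnai2 (8.58-fold [7.64–9.67]), the transcription factor Meis2 (14.6-fold [11.8–18.3]), the G protein gamma subunits Gng13 (10.32-fold [8.94–11.98]) and Gng2 (11.95-fold [10.34–13.9]), and the semaphorin receptor Nrp2 (6.14-fold [5.25–7.23]). V2R cells had higher Gnao1 (22.5-fold [20.3–24.97]), the transcription factor Tfap2e (90.97-fold [58.5–148.95]), the Slit receptor Robo2 (33.8-fold [27.7–41.7]) and the keratins Krt8 (8.85-fold [7.99–9.81]) and Krt18 (4.11-fold [3.87–4.36]). Omp differed by 1.15-fold [1.09–1.21]. With the larger corrected groups these folds were smaller: Gnai2 4.68, Meis2 4.59, Gng13 4.70, Gng2 5.24, Gnao1 12.6, Tfap2e 52.5, Robo2 13.4 and Krt8 5.84, while Nrp2 was 6.01 and Krt18 3.10. Corrected calls restricted to the V1R-type-like and V2R-type-like cells gave Krt8 19.5-fold [17.7–21.6]. Those groups were formed from the cells' expression of genes other than receptors, so a larger fold between them is partly built in.

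Among 14666 genes with enough counts, the size rule took 2401 genes higher in V1R cells and 863 higher in V2R cells. The largest folds rested on few counts in the lower class. Nfix (166.1-fold [45.9–1373]), Pde1a, Ptk2b, Mrpl47, Thap4, Lysmd4, Tspan12, Trdmt1, Gm45185, Cobl, Msantd2 and Fbxw17 led in V1R cells, down to 87.7-fold [15.7–3472], each with 1 or 2 counts in V2R cells. Hhipl2 (536-fold [93.8–21391]), Plxnb3, Ptpn13, Gm11739, Adgre1, Gm17100, Gm2762, Gm7972, AY074887, Gstm7, Gm43301 and Kcna1 were the 12 with the largest folds in V2R cells. Adgre1 had 0 counts in V1R cells and was at least 314.5-fold higher, against a floor of 3 counts over the group, while the others had 1 or 2 counts that were not raised to it, so the order among the 12 carries no meaning. Requiring at least 10 counts in 25% of the cells of the higher class, a rule chosen after the values were seen, left 496 genes, of which 52.8% were higher in V2R cells, so the excess on the V1R side did not hold. Under the corrected calls with this rule the V2R share was 57.8%. With no minimum count the size rule took 2428 genes higher in V1R and 5557 higher in V2R cells. In that setting a gene with 1 count in V1R cells and 0 in V2R cells is taken as higher in V2R cells. The reason is that the floor of 3 counts is scaled to the smaller V2R total, so that split is not a result about the cells. With at least 10 counts in 25% of cells, the largest V2R folds belonged to B4galt6 (143.02-fold [73.98–316.9]), Batf3 (139.4-fold [84.7–246.4]), Sphkap (92.4-fold [67.8–129]), Tfap2e, and the NMDA receptor subunit Grin3a (73.2-fold [46.9–120]), and the largest V1R folds to Nfix, Matn2 (69.8-fold [27.2–256.3]) and Pon3 (35.3-fold [18.6–77.3]). Under the corrected calls Batf3 was 25.3-fold, Sphkap 46.8-fold, Grin3a 29.1-fold, Nfix 6.20-fold and Matn2 4.57-fold.

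Gene groups fixed beforehand were compared next. Here and in the next paragraph, values for the V1R-type-like and V2R-type-like cells alone select cells by their expression, so they are no separate support. Chaperones and stress genes of the endoplasmic reticulum had a median log2 ratio of V1R to V2R of -0.48, at percentile 0 of 10000 random expression-matched lists, and -0.50 under the corrected calls, again at percentile 0. Creld2 (3.79-fold [3.34–4.29]) and the disulfide isomerase Pdia6 (2.06-fold [1.94–2.20]) were higher in V2R cells, the calcium-binding chaperone Calr (2.58-fold [2.16–3.10]) was higher in V1R cells, and 12 of 15 members passed neither way. Hspa5, the main chaperone of this compartment, was 1.54-fold [1.47–1.61] and Manf 1.80-fold [1.69–1.91] higher in V2R cells, under the size rule's limit. Of 15 signal transduction genes, Gnai2 and Gng13 were higher in V1R cells and Gnao1 and Stim1 (3.29-fold [2.95–3.67]), the calcium store sensor, in V2R cells, with the list's median at percentile 50.48, and 81.67 corrected. Adhesion and guidance genes were at percentile 12.63, and at 23.93 with corrected calls. They were at 95.75 with corrected calls in the V1R-type-like and V2R-type-like cells alone. As deposited, Nrp2, Slit1 (6.70-fold [4.21–11.4]) and Tenm2 (2.80-fold [2.39–3.30]) were higher in V1R cells and Robo2 in V2R cells. Under the corrected calls Slit1 was 2.496-fold and Tenm2 1.37-fold, while 4 of 19 members passed as higher in V1R cells and 1 in V2R cells.

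Other groups depended on the correction. Antigen presentation genes H2-K1 (4.11-fold [3.46–4.91]), Tap1 (3.17-fold [2.18–4.78]) and H2-D1 (2.56-fold [2.27–2.88]) were higher in V1R cells at percentile 96.77, but with corrected calls no member passed, and H2-K1 was 1.40-fold, while 2 of 6 passed with the V1R-type-like and V2R-type-like cells alone. B2m, which pairs with H2-K1 and H2-D1, was 1.72-fold [1.63–1.81] higher in V2R cells, under the size rule's limit. The immature markers Dcx (3.69-fold [2.95–4.68]), Stmn2 (2.19-fold [1.98–2.42]) and Gap43 (2.13-fold [1.85–2.46]) were higher in V1R cells at percentile 99.99, and 0 of 6 passed under the corrected calls, where the percentile was 99.9. The activity genes Fos (3.20-fold [2.76–3.75]), Fosb (3.33-fold [2.38–4.8]) and Nr4a1 (5.92-fold [1.58–49.9]) were higher in V1R cells at percentile 91.04, and none passed after correction, while 2 of 13 passed with the V1R-type-like and V2R-type-like cells alone. Of the chromatin factors, Smchd1 (2.56-fold [2.07–3.22]) and Suv39h1 (5.32-fold [1.41–44.9]) were higher in V1R cells and Lbr (4.27-fold [3.06–5.93]) in V2R cells at percentile 11.79. After correction none of these passed, with Suv39h1 higher in V2R cells but short of the rule, while 1 other member passed as higher in V1R cells. The list's median turned to the V1R side, at percentile 88.06. Transcription factors lay at percentile 39.99, and 77.74 corrected, with Nfia (11.5-fold [4.42–42.4], and 2.64-fold corrected) and Pou2f1 (2.04-fold [1.67–2.51]) higher in V1R cells, and Pou2f1 1.70-fold higher in V2R cells after correction. Sustentacular markers went both ways, Krt8 and Krt18 to V2R cells and Cbr2 (2.14-fold [1.74–2.65]), Cyp2a5 (6.74-fold [2.58–25]) and Sox2 (11.7-fold [3.94–57.1]) to V1R cells, at percentile 96.05. After correction Cbr2 and Sox2 did not pass and the percentile was 50.13, and 98.93 with the V1R-type-like and V2R-type-like cells alone. The chaperone Rtp1, in the main olfactory list, was 9.94-fold [8.57–11.6] higher in V1R cells and 6.13-fold corrected, and Cnga2 was 62.1-fold [27–175.6] higher in V2R cells through 1 cell. That list lay at percentile 0.01, and at 0 with corrected calls, where Cnga2, Gnal and Stoml3 were higher in V2R cells, but at 93.19 with the V1R-type-like and V2R-type-like cells alone. The corrected V2R cells included immature-like cells with at least 10 counts each of Cnga2, Gnal and Stoml3. In V2R-type-like cells, at least 10 counts were present in 0% for Cnga2 and Stoml3 and 1.32% for Gnal. The corrected percentile is therefore not shown to be a trait of V2R cells in general. In the immune list, at percentile 23.42, Cd74 (8.76-fold [3.37–32.4]) was higher in V1R cells and did not pass after correction. With corrected calls Csf1r (33.4-fold [5.86–1334]) and C1qb (5.39-fold [2.21–17.1]) were higher in V1R cells and Tyrobp (10.2-fold [8.02–13.2]) and Lyz2 (4.09-fold [2.78–6.06]) in V2R cells, each with at least 10 counts in at most 8.54% of cells, at percentile 47.48. With the V1R-type-like and V2R-type-like cells alone only Tyrobp and Lyz2 passed, both higher in V2R cells, at percentile 2.60. No progenitor, endothelial, erythroid or gland marker passed before correction. With corrected calls the endothelial marker Pecam1 (5.33-fold [3.09–9.42]) passed as higher in V2R cells, on 40 counts in those cells, and no progenitor, erythroid or gland marker did.

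V2R neurons are known to co-express a member of family C, and some also non-classical H2-Mv class I genes, so the V2R cells were examined for both. All 23 V2R cells (100% [85.2–100]) held at least 3 counts of a family C gene. Vmn2r1 was present in 22 (95.7% [78.1–99.9]), a gene of Vmn2r2 to Vmn2r6 in 18 (78.3% [56.3–92.5]), and both in 17 (73.9% [51.6–89.8]). Background was 2.38% of V1R cells for Vmn2r1 and 16.7% for Vmn2r2 to Vmn2r6, and 0% and 13% of sustentacular-like cells, whose median total was 113367 against 144552 in V2R cells. With corrected calls, 68 of 82 V2R cells (82.9% [73–90.3]) had family C counts, against 21.2% of V1R cells. Of these 82 cells, 65 were V2R-type-like, 5 V1R-type-like, 8 immature-like and 4 sustentacular-like. Corrected V2R cells without family C counts are therefore not shown to be V2R neurons that lack it.

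Among H2-Mv genes, H2-M10.3 (3.97-fold [3.52–4.48]), H2-M10.4 (20.4-fold [16.9–24.8]), H2-M10.5 (12.9-fold [10.41–16]) and H2-M10.6 (58.2-fold [34.2–106.7]) were higher in V2R cells, and the list's median lay at percentile 0.01. These folds rested on few cells. Of 23 V2R cells, at least 10 counts were present in 6 for H2-M10.3, 2 for H2-M10.4, 5 for H2-M10.5 and 3 for H2-M10.6. H2-M9 was 5.67-fold [1.51–47.8] higher in V1R cells through 1 cell with at least 10 counts. With corrected calls 9 of 9 members were higher in V2R cells, including H2-M9 (27.2-fold [21.5–34.8]) and H2-M1 (18.9-fold [15.2–23.7]), at percentile 0, while H2-M10.5 was 5.66-fold and H2-M10.6 19.5-fold. Of the 82 corrected V2R cells, 5 held at least 10 counts of H2-M9, 5 of H2-M1 and 16 of H2-M10.4. At least 10 counts of an H2-Mv gene were present in 34.8% [16.4–57.3] of V2R cells and 12.7% [7.44–19.8] of V1R cells, and in 47.6% and 17.4% with corrected calls. In the corrected V2R cells, split by family C genes with at least 10 counts, H2-Mv genes were present in 9 of 11 cells with Vmn2r2 to Vmn2r6 alone (81.8% [48.2–97.7]) and 21 of 37 cells with both kinds (56.8% [39.5–72.9]). They were present in 5 of 18 cells with Vmn2r1 alone (27.8% [9.69–53.5]) and 4 of 16 with neither (25% [7.27–52.4]). Family C use was also counted by genomic cluster, with clusters picked after their values were seen. The largest group, 20 cells with a V2R receptor from chromosome 7 (7231327–13220657), was mixed: 2 had Vmn2r1 alone, 6 had Vmn2r2 to Vmn2r6 alone, 7 had both and 5 neither. Of 5 cells with a receptor from chromosome 5 (108791843–109578589), 4 had Vmn2r2 to Vmn2r6 alone and 0 had Vmn2r1. Of 18 cells with a V2R receptor from chromosome 17 (17703747–21314912), 7 had Vmn2r1 alone, 8 had both and 0 had Vmn2r2 to Vmn2r6 alone.

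The last question was whether cells held more than 1 receptor. A second receptor of at least 10 counts and 10% of the top receptor was present in 87.1% [83.4–90.3] of single-cell chambers with a top receptor of 10 counts, against 88.5% [77.8–95.3] of multiple-cell and 89.5% [85.6–92.7] of empty chambers. It came from the same genomic cluster as the top receptor in 39.9% [34.7–45.4] of cases, against 9.08% of random pairs, and shared transcript sequence with it in 35.2% [30.1–40.6], against 1.69%. With sequence-sharing receptors left out, the same-cluster share was 9.15% [6.12–13], against 7.66% of random pairs without shared sequence. Under both corrections a second receptor was present in 66% [61–70.7] of single-cell, 82% [70–90.6] of multiple-cell and 58% [51.7–64.2] of empty chambers, and its median count in single-cell chambers was 28.5% of the top receptor's.

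**Figure D4:**
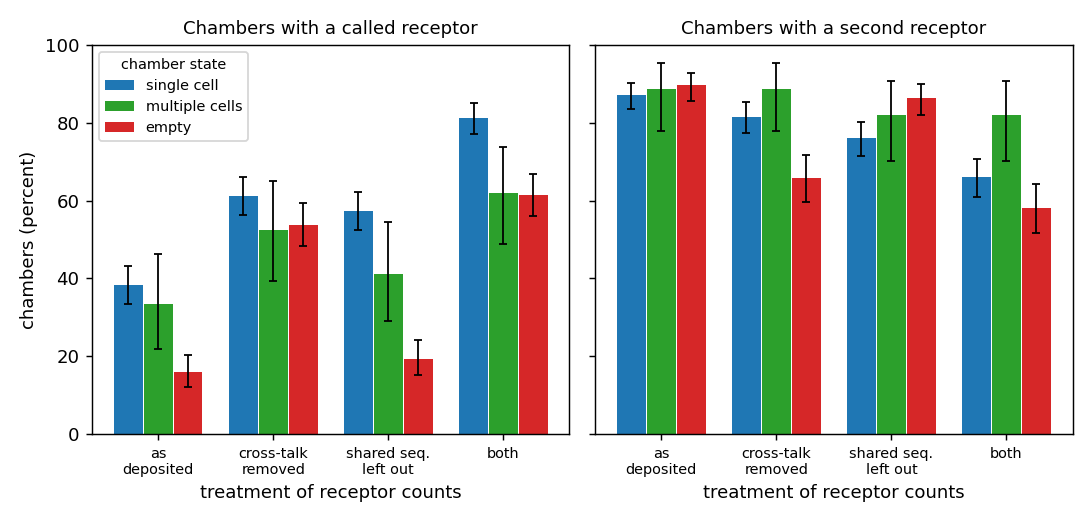
Percent of chambers with a called receptor (left) and with a second receptor (right) under each treatment of the receptor counts, by chamber state, with exact 95% intervals as bars. Calls in single-cell chambers went from 38.3% as deposited to 81.2% with both corrections, and second receptors from 87.1% to 66%.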

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

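Of the tests in this part, those on shared sequence, on cross-talk and on more than 1 source of RNA in empty chambers were chosen only after the result was seen.

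In the chambers labelled putative single cell, which were left out of the receptor classes in the values reported, Gnao1 exceeded Gnai2 in 10 of 18 (55.6% [30.8–78.5]), a signal in data outside the main measurement that lay above the 11.1% [7.88–15.0] of empty chambers and the 20.3% [16.4–24.6] of single-cell chambers. In 1 of these 10 chambers (10% [0.253–44.5]) the top receptor had a higher count in another chamber of the same title row or number. That cannot decide on cross-talk, since the top receptor was taken after the cross-talk filter, which drops receptors high in those chambers. Cross-talk of Gnao1 itself was not tested. Position by title row is argued against, since single-cell chambers in the title rows that hold a putative chamber had more Gnao1 in 18.05% [11.9–25.6]. Position by title number was not tested. Lower depth stays open, because the share among single-cell chambers in the lowest 25% of totals, 23.2% [15.3–32.8], overlapped the interval of the 18 chambers. With corrected calls 12 of 15 called putative chambers were V2R (80% [51.9–95.7]), against 25.6% of called single-cell chambers, while as deposited 2 of 4 were; why such cells would be V2R-type was not tested.

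Second receptors were present in 87.1% of single-cell chambers, and 39.9% of them came from the genomic cluster of the top receptor. The excess from the same cluster lay among receptors that share sequence, since leaving these out brought the share to 9.15% [6.12–13], near the 7.66% of random pairs. Reads shared between paralogs may account for that excess. True co-expression of such paralogs would be left out as well, so the test cannot tell these apart. Cross-talk within a title row or number is argued against as the whole source, since without its removal 62.7% [56.9–68.2] of the second receptors that shared no sequence had a higher count in such a chamber, against 43.5% with the same counts placed at random; a part from cross-talk stays open. A second cell of the other class, to which this explanation was narrowed after the result was seen, was tested only in called V1R chambers. Of 44 with a V2R second receptor, 6 (13.6% [5.17–27.4]) held at least 20 counts of Gnao1. The share was 86.6% [77.3–93.1] in V2R cells and 6.59% in V1R chambers without a second receptor. Only 3 multiple-cell chambers could serve as a control for known second cells, and 0 of them held at least 20 counts (0% [0–70.8]). The test cannot decide on a second cell of the other class, since chambers with similar receptor counts from both classes can fail the call. The control is also too small. A second cell of the same class and true co-expression stay open and were not tested.

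Of the empty chambers, 25 had cell-like totals, and all 25 held at least 40 counts of Omp, against 89.8% of single-cell and 16.7% of the other empty chambers. Of these, 28% [12.1–49.4] had a higher count of the top receptor in another chamber of the row or number. The share was 59.1% in the other empty chambers and 18.1% [14.1–22.8] in called single-cell chambers. That cannot decide on cross-talk, since the top receptor was again taken after the cross-talk filter, and larger counts are harder to exceed. More than 1 source of RNA cannot be told apart from a single one, since 72% [50.6–87.9] had a second receptor after the corrections, against 66% of single-cell chambers. A cell missed when the chambers were scored is a candidate explanation that was not tested, and 11 of the 14 such chambers with a corrected call were V1R.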

How the results depend on the processing

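All alternatives with cross-talk removed, with shared sequence left out, with sustentacular-like cells left out, with 10 counts in 25% of cells, or restricted to groups of cells were chosen after the result was seen. Of 71 planned values 60 stayed close to those reported and 11 moved, and of 36 added values 17 stayed close and 19 moved. Some of the 60 could not move. Dropping or raising the minimum for total counts and genes kept the same single-cell chambers, which held at least 6521 counts and 2719 genes. Dropping the fractional part of counts changed nothing, since all values were whole numbers. The values under those settings therefore say nothing about how stable the results are. The balance of the genes taken by the size rule turned from V1R to V2R cells with 10 counts in 25% of cells, both as deposited and with both corrections. It also turned as deposited with no minimum count, but there the floor of 3 counts, scaled to the smaller V2R total, puts genes with few counts on the V2R side. Causes of the other moves were not tested, except where a setting changed the rule or the cells counted, as stated below. Fewer receptor counts also remain under each correction by its own construction. Correcting for identifier saturation gave a median total of 153956. A top receptor with 80% of receptor counts gave 4.82% of cells called, 94.7% V1R, a median share of 85.04% and 4.75% of functional genes called. Second receptors were present in 10.53% of the cells called at that share. The 87.1% reported was instead a share of all chambers with a top receptor of 10 counts. A top receptor with 80% of receptor counts leaves little room for a second, so this fall follows from the selection. A second receptor of 3 counts was present in 100% of cells, and linking genes within 2 Mb gave 100% clustered. In title numbers 1 to 10 alone 5367 genes were taken, and 6114 in 11 to 20 alone. These sets hold fewer cells, and the size rule's agreement between the 2 sets of title numbers cannot apply within 1 of them. Both counts thus come from a looser rule and do not show how stable the size rule is. The size rule took 7985 genes with no minimum count (2428 higher in V1R and 5557 in V2R cells) and 496 with 10 counts in 25% of cells. With that last rule the share of tested genes taken was 3.38%, and 1.17% with both corrections. It could not be run with the 80% share, which left too few V2R cells. With cross-talk removed the values were 61.2% called, a median share of 73.8%, 81.5% with a second receptor, 34.5% of functional genes and 77.8% of V2R cells with family C. With shared sequence left out they were 57.4% called, 75.2% V1R, a median share of 67.3%, 76.03% with a second receptor and 37.03% of functional genes. With both they were 81.2% called, 73.8% V1R, a median share of 81.2%, 66% with a second receptor, 44.3% of functional genes, 82.9% with family C and 94.3% matching class and group. The V2R values as deposited rest on 23 cells. No paired analysis was possible because the labels do not link chambers to animals or pools.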

Other observations

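All values in this part were chosen after the data were seen. Although the sorted tissue was vomeronasal, 3 single-cell chambers held at least 10 counts each of Cnga2, Gnal and Stoml3, genes of main olfactory neuron transduction, and all 3 lay in the immature-like group. Of the rest of the fixed main olfactory list, Adcy3 held at most 1 count in them and Rtp1 at least 57. The top olfactory receptor was Olfr1509 in 1 of them (79 counts) and Olfr1372-ps1 in the others (62 and 49 counts). The chamber with 62 counts of Olfr1372-ps1 had Vmn2r55 as its top vomeronasal receptor, with 56 counts of Vmn2r1 and 84 of Gnao1. Olfactory receptor genes reached 10 counts in 20 single-cell chambers (5.08% [3.13–7.73]) and 11 empty chambers (3.38% [1.70–5.98]).

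In 4 further single cells an olfactory receptor exceeded every vomeronasal receptor without Cnga2. Among these, Olfr1512 had 56 counts in a cell with 95 counts of Gnai2 and 92 of Stoml3, Olfr1339 had 51 in a cell with 98, and Olfr1372-ps1 had 40 in a cell with 85. The genes V1ra8, V1rd19 and V1rg10, V1R genes under an older naming that were left out of the receptor call, reached 10 counts in 3 single-cell chambers, with up to 57 counts of V1ra8.

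The sustentacular-like cells passed a sort for GFP under Omp, yet had a median of 16 Omp counts and a top vomeronasal receptor at a median of 44 counts. Beside the fixed markers that named the group, the genes that set it apart included Anxa1, Klf4, Wfdc2 and Krt23, which reached 10 counts in 86.96%, 91.3%, 91.3% and 91.3% of their cells, against 0%, 0.539%, 1.89% and 1.08% of other cells. H2-Aa, a class II antigen presentation gene, reached 10 counts in 95.7% of them against 2.70% of other cells.

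Pooled over 4756 genes and the single cells, 33.8% of the values above 0 were 1, 11.9% were 5 to 12, and 16.6% were 31 to 50, with a median of 33 for values of at least 10. Whether 1 captured molecule gave more than 1 identifier was not tested. The minimum counts, the family C rule and the counting intervals all take each count as 1 molecule, and would mean something else if it did.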
